A study of Zea mays with 29 samples.

How the data were processed

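The samples were 27 RNA libraries and 2 DNA libraries from maize (Zea mays) leaf. The plants differed in ploidy or in the number of copies of the long arm of chromosome 1, called 1L below. The RNA libraries form 2 dosage series, each with its own diploid controls. RNA was extracted with TRIzol and poly(A)-enriched libraries were made with TruSeq kits, per the labels. The submitters' processing notes list Bowtie, TopHat, Cufflinks and Cuffdiff without versions; the role of each tool and the genome build are not given in the sources used here.

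The deposited counts tables hold raw counts, whole numbers of reads per gene model, with 1 column per library. The deposited RPKM tables hold reads per kilobase of gene model scaled to the library total, RPKM, and were checked to equal the counts scaled by 1 length per gene and by each library's table total. The deposited DNA table gives RPKM in bins of 1000000 bp and, per the file headers, the ratio of trisomic to diploid RPKM in each bin. Library totals ran from 13199571 to 18923160 counted reads in series 1 and from 14115560 to 19860440 in series 2, so that 1 CPM, a count scaled to the standard library total, rested on about 13 to 20 reads. The DNA table gives no read numbers, so its depth is unknown. The reads carry no molecular identifiers, and counting errors cover only part of their variation.

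Fold changes were tested in edgeR 4.0.16 (R 4.3.3) with TMM normalization, the filterByExpr filter and quasi-likelihood F-tests with robust dispersion. Tests were two-sided and genes with a Benjamini-Hochberg adjusted p below 0.05 were called. Each series was fitted as a whole with group as the only term. The filter kept 22435 genes in series 1 and 21825 in series 2, and the biological coefficient of variation was 0.318 and 0.273. Linear trends over the copy number of 1L used the diploid, trisomic and tetrasomic libraries of series 1, and all libraries of series 2. In counts simulated with the fitted dispersions, 200 genes were changed in each comparison. Between 0 and 4% of genes changed by 1.5-fold were recovered, between 6 and 18% of those changed by 2-fold, and between 58 and 78% of those changed by 4-fold. These shares hold where few genes change, since the adjustment is stricter then, and do not carry over to the block described below. There 43.8, 37.6 and 48.4% of tested genes were called in tetrasomics, disomic haploids and monosomics. In trisomics of series 1 and 2 it was 12.4 and 0.890%. False calls numbered 0 to 11 per simulation, with 11 in series 1 trisomics and 0 to 4 in the others. The 11 stood beside 4, 9 and 38 recovered genes of the 1.5-, 2- and 4-fold classes. That is a larger share of the calls than 0.05. The 4-fold class was added after the low recovery of the others had been seen.

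The gene tables list 40306 identifiers without names, products or positions. None of them occurs in the reference table used here (0 matched), so the 26 gene lists fixed before the data were examined could not be tested and 1L genes could not be picked by position. The rule for naming genes then allowed at most 2 identifiers that rose and 2 that fell. Each is the largest rise or fall in its comparison outside the block described next, among genes with adjusted p below 0.05, a mean of at least 5 CPM and groups that do not overlap. The comparisons they come from were picked after their values had been seen.

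In place of positions, the order of the identifiers was used, a choice made after the data had been seen. The design had foreseen only counts of called genes for the case without positions, so all results on the block depart from it. In each series a least-squares search found the run of consecutive identifiers whose expression differed most from the rest. It compared tetrasomics with diploids in series 1 and trisomics with monosomics in series 2, on log2 CPM with 0.5 added, for genes with a mean of at least 1 CPM, with differences limited to between -2 and 2. On simulated values the search placed the edges within 1 gene. To keep the definition apart from the test, each series was analysed with the edges found in the other. The run is called the block. The tables used here pair no gene with a chromosome, and that the block is the varied part of 1L is inferred from its response to copy number.

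The relative expression of the block was computed for each library as the mean log2 CPM of its kept genes minus that of all other kept genes, with a prior count of 2. Group means were compared by exact two-sided permutation tests that take 2 times the smaller tail, with Benjamini-Hochberg adjustment over the 6 comparisons. Differences between effects were tested by permuting libraries within each dose. Each block gene was classed by the 95% confidence interval of its log2 fold change. A gene was proportional when the interval held the log2 of the copy ratio and not 0, compensated when it held 0 and not that ratio, and undecided when it held both. The breakpoint on chromosome 1 was sought by a least-squares change point in the log2 DNA ratio. Log2 fold changes of genes outside the block were compared between comparisons by Pearson and Spearman correlation across genes. Where diploids were shared, 5 simulations of unchanged groups gave the correlation that sharing produces when genes vary independently. Departures of a library across many genes did not enter these simulations.

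Alternatives fixed before the data were examined were DESeq2 1.42.0, size factors by relative log expression, no filter, a stricter filter (5 CPM in at least 3 libraries), limma-trend (limma 3.58.1) on log2(RPKM + 1), a fit of the compared libraries alone, the replicate number as a block, the S number of the library name as a block in series 2, and leaving out each library. For the relative expression of the block they were the median over genes, the stricter filter, summed counts, log2 RPKM with 1 or 0.1 added and replicate numbers as a block, and for the breakpoint running medians over 50 bins. Alternatives chosen after seeing the data were TMM outside the block, a block shortened by 200 identifiers at both ends and DNA bins of at least 0.3 RPKM. They stand in for TMM outside chromosome 1, a margin in base pairs and a minimum of 1 RPKM. The last of these left 1 bin of chromosome 1 and was not run. The correlations of the 2 trends and of tetrasomics with monosomics were also added afterwards. Replicate and S numbers were checked for pairing of libraries across groups, with 2 to 4 pairs in each check, and the outcome was mixed. In series 1, libraries with the same replicate number were more alike than others in some pairs of groups and less alike in others. In series 2 they were more alike on average in each pair of groups, and S numbers went both ways. Pairing was thus neither shown nor excluded. No 2 libraries of a group were duplicates, since the lowest chi-square per gene between replicates was 16.1. Group labels were also reassigned among the libraries, in every possible way where there were 35 or fewer and in 80 draws with a fixed seed where there were more, the real grouping included. Figures were drawn with matplotlib 3.10.9.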

Results

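Poly(A) RNA was sequenced from leaves of maize plants that carried different numbers of copies of 1L, the long arm of chromosome 1, or of the whole genome. Series 1 held 4 diploid libraries with 2 copies of 1L, 5 trisomic with 3, 3 tetrasomic with 4, 3 haploid with 1, and 2 disomic haploid with 2 in an otherwise haploid genome. Series 2 held 4 monosomic libraries with 1 copy, 3 diploid and 3 trisomic. The series design calls the libraries biological replicates. Each library had between 13199571 and 19860440 counted reads and between 24756 and 26961 genes with at least 1 count. Diploid replicate 1 of series 1 stood apart from the other diploids of its series, with a chi-square per gene of 74.6 to 99.2 against each of them, compared with 17.1 to 24.8 among the others. Such distances also occurred within other groups, up to 81.3 in series 1 trisomics, 105.1 in haploids and 84.8 in monosomics. In series 1 tetrasomics and series 2 trisomics they reached only 28.5 and 19.5.

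A single run of consecutive gene identifiers followed the copy number of 1L. In series 1 it ran from identifier number 2682 to 5868 and in series 2 from 2712 to 5868, with the same last gene. It held 3187 identifiers in series 1, 7.91% of the 40306 listed, and 3157 in series 2. In the comparison used to find it, its genes differed from the diploids by a mean log2 of 0.92 in tetrasomics, against 0.04 outside it. Between trisomics and monosomics the means were 1.21 and -0.14. The tables used here pair no gene with a chromosome, so that this block is the varied part of 1L is inferred, and each series was analysed with the edges found in the other.

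**Figure D1:**
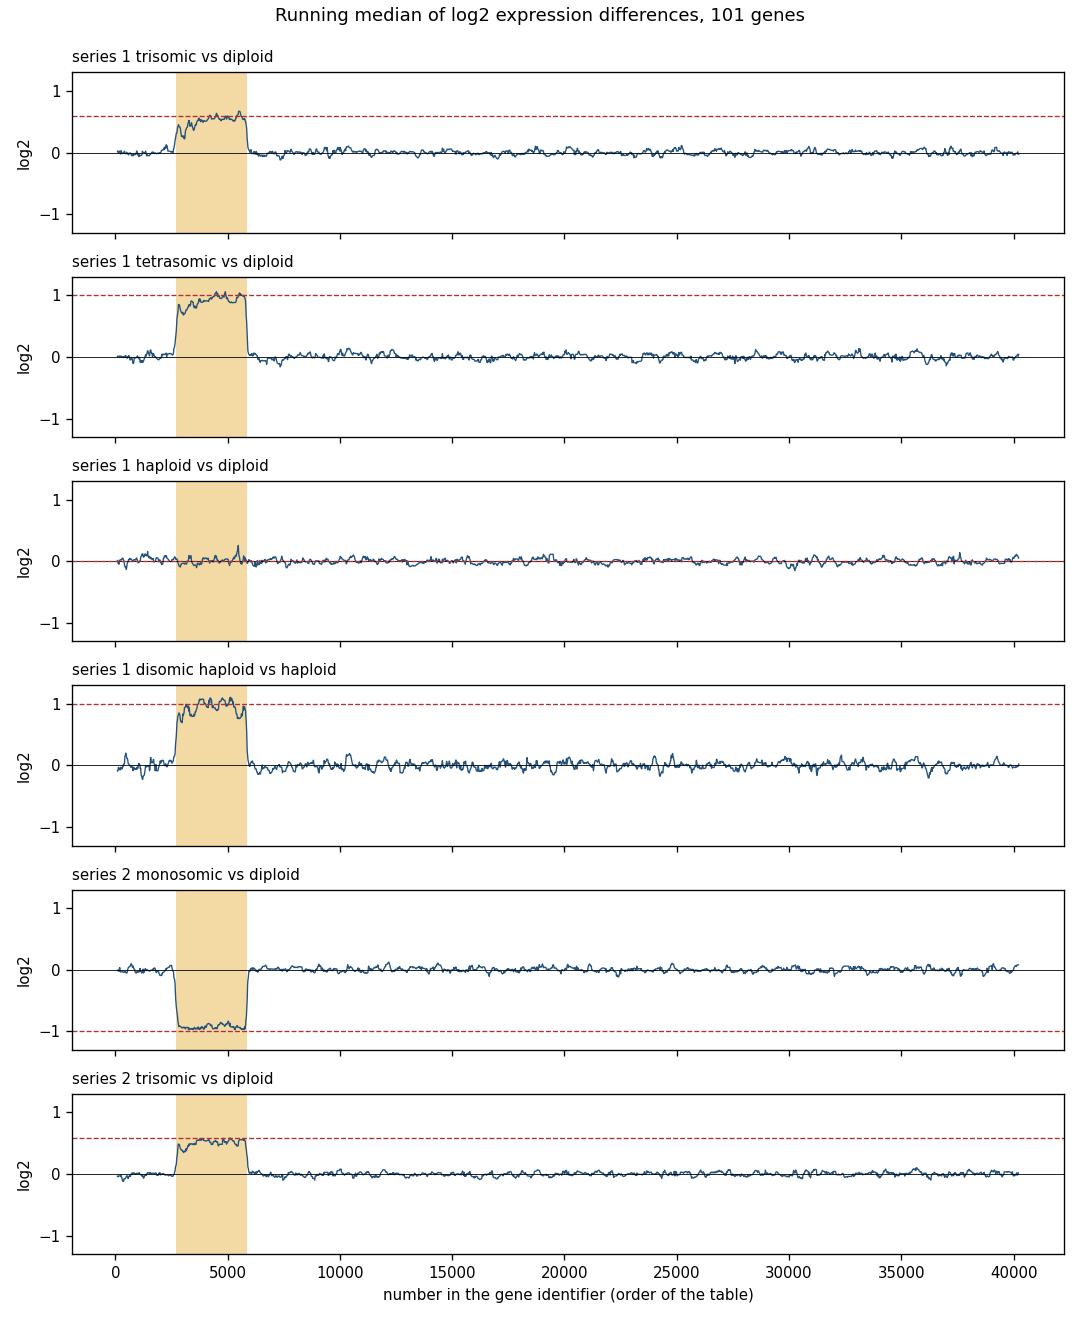
Running median over each gene and the 50 on either side of the log2 expression difference in each comparison, relative to the median outside the block, against the number in the gene identifier. The shaded block spans the edges found in the other series and the dashed line marks the log2 of the copy ratio of 1L; outside the block the largest shift of a window was -0.23, in disomic haploids against haploids.

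In trisomic plants of series 1, whose 1L copy number is 1.5 times that of diploids, the block was expressed at 1.38 times its diploid level relative to other genes. Its relative expression was 0.45 ± 0.01 (log2, SD, n = 5) in trisomics and -0.02 ± 0.02 (SD, n = 4) in diploids. The difference of 0.47 (SE 0.01) was 80.3% of the log2 of the copy ratio, 0.58, and all trisomic libraries lay above all diploid ones. Its size depended on the summary, at 0.64 with summed counts, above the log2 copy ratio, 0.54 with the median over genes and 0.34 with mean log2(RPKM + 1). An exact permutation test gave p = 0.0159, the smallest that 5 against 4 libraries can give, and 0.0952 after adjustment over the 6 comparisons. With replicate numbers as a block, which leaves 4 pairs, the difference was 0.47 with an exact p of 0.125, the smallest those pairs allow.

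In edgeR 235 of the 340 genes called in this comparison lay in the block, but 320 of 699 did without diploid replicate 1, 330 of 640 without trisomic replicate 1 and 545 of 1090 with DESeq2. Of the 340, 233 block genes were higher and 2 lower, and outside the block 40 were higher and 65 lower. The median log2 fold change was 0.52 over the 1893 block genes tested and -0.02 over the 20542 others. The count was 65, 120, 49, 113 and 152 without diploid replicates 2, 3 and 4 and trisomic replicates 2 and 3. It was 72 with the replicate block, 131 with the compared libraries alone and 189 without a filter, and the direction outside the block turned with limma-trend (82 higher, 42 lower), with the compared libraries alone (25 and 16), with the replicate block (14 and 10) and without diploid replicate 3 (17 and 16), diploid replicate 4 (7 and 6) or trisomic replicate 3 (19 and 16).

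Tetrasomic plants carry 2 times the diploid number of 1L copies. Relative to other genes, the block was expressed at 1.84 times its diploid level. Its relative expression was 0.86 ± 0.03 (log2, SD, n = 3) against -0.02 ± 0.02 (SD, n = 4), a difference of 0.88 (SE 0.02) or 88.2% of the log2 copy ratio, with no overlap of libraries. It was 1.01 with summed counts, 0.96 with the stricter filter and 0.63 with mean log2(RPKM + 1), against a log2 copy ratio of 1. The exact permutation p was 0.0571, the smallest that 3 against 4 libraries can give, and 0.114 after adjustment over the 6 comparisons. In the block 827 genes were called higher and 3 lower in edgeR, and outside it 200 were higher and 370 lower, 1400 in all. The median log2 fold change was 0.89 in the block and -0.06 outside it.

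Among genes outside the block that met the naming rule, the largest rise in tetrasomics was that of Zm00004b008168. It stood at 100.8 ± 27.9 CPM (counts scaled to a common library total; SD, n = 3) in tetrasomics and 4.27 ± 1.88 (SD, n = 4) in diploids, a log2 fold change of 4.42 (SE 0.58, edgeR adjusted p = 0.000298). It was also higher in disomic haploids than in haploids, at 54.4 ± 38.4 (SD, n = 2) against 1.93 ± 1.2 CPM (SD, n = 3), a log2 fold change of 4.81 (SE 0.70, edgeR adjusted p = 0.000979), a call lost in a fit of the compared libraries alone, which called 0 genes. The count of genes called in tetrasomics was 2457 without diploid replicate 1, 782, 890 and 719 without tetrasomic replicates 1, 2 and 3, and 2212 with DESeq2. With limma-trend the direction outside the block turned, with 230 genes higher and 176 lower.

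**Figure D2:**
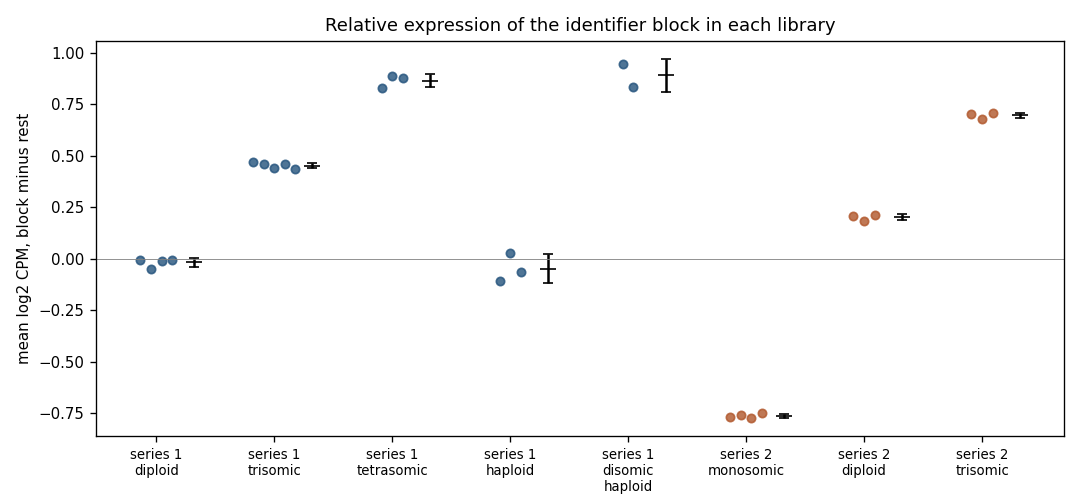
Relative expression of the block in each library, as mean log2 CPM of block genes minus that of all other genes, with 1 point per library and the group mean and SD in black. Series 1 is blue and series 2 is orange; in every comparison of different 1L dosage the groups do not overlap, while haploids run from -0.11 to 0.03 and diploids of series 1 from -0.05 to -0.00.

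Haploid plants carry 1 copy of the whole genome, which leaves 1L in balance, and the block did not stand out in them. Its relative expression was -0.05 ± 0.07 (log2, SD, n = 3) in haploids and -0.02 ± 0.02 (SD, n = 4) in diploids. The difference of -0.03 (SE 0.04) was smaller than the spread between haploid libraries (exact permutation p = 0.457, also after adjustment), and its sign depended on the summary used, at 0.03 with the median over genes. In edgeR 424 genes were called, of which 308 were higher and 116 lower in haploids, with 21 higher and 13 lower in the block. The block's share of calls, 1.80% of its tested genes, was close to the 1.90% outside it.

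The largest fall in haploids outside the block by the same rule was that of Zm00004b010606, at 0.263 ± 0.289 CPM (SD, n = 3) in haploids and 32.9 ± 17.0 (SD, n = 4) in diploids. Its log2 fold change was -7.04 (SE 1.16, edgeR adjusted p = 0.0129). It was -8.24 without haploid replicate 3, -6.45 without haploid replicate 2 and -3.97 with limma-trend on log2(RPKM + 1). The haploid count was 990 without haploid replicate 2, and 129 and 108 without haploid replicates 1 and 3. It was 161, 96, 175 and 111 without diploid replicates 1, 2, 3 and 4, 8 in a fit of the compared libraries alone and 1113 with DESeq2.

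Disomic haploids carry 2 times the haploid number of 1L copies. Relative to other genes, the block was expressed at 1.92 times its haploid level. Its relative expression was 0.89 ± 0.08 (log2, SD, n = 2) against -0.05 ± 0.07 (SD, n = 3), a difference of 0.94 (SE 0.07) or 93.8% of the log2 copy ratio, without overlap, and it ran from 0.66 with mean log2(RPKM + 1) to 0.97 with the stricter filter. The exact permutation p was 0.2, the smallest that 2 against 3 libraries can give, and 0.24 after adjustment. In edgeR 1512 genes were called, with 708 higher and 4 lower in the block and 338 higher and 462 lower outside it. The count was 957 without haploid replicate 1, 506 and 955 without disomic haploid replicates 1 and 2 (which leaves 1 library, assumed to vary like the other groups), 2678 with DESeq2 and 0 in a fit of the compared libraries alone, where 3997 genes had an unadjusted p below 0.05. With TMM computed outside the block, an alternative chosen after seeing the data, 403 genes were higher and 403 lower outside it, and without disomic haploid replicate 1 the direction there turned, with 87 higher and 49 lower, again with 1 library in that group.

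Whether the same relative change of 1L acts differently in haploid and diploid plants was tested as the disomic haploid effect minus the tetrasomic effect. In edgeR 0 of 22435 genes were called, with 1067 at an unadjusted p below 0.05, against 10 called in DESeq2 and 2 in limma-trend. The edgeR count was 2 without haploid replicate 2, and 12 without either disomic haploid replicate, where the spread of the library left is taken from the other groups. For the block the difference was 0.06 (log2), with an exact permutation p of 0.349 over 350 permutations, or 0.697 adjusted over 2 such tests, which does not show that the effects are equal. Across 20534 genes outside the block the log2 fold changes of these comparisons, which share no library, correlated with a Pearson r of 0.57 and a Spearman rho of 0.52. Both called 82 of these genes higher, where 3.29 would be shared by chance, and 115 lower, where 8.32 would. Genes are not independent replicates, so no p is given.

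Monosomic plants of series 2 have 1 copy of 1L, and the block was expressed at 0.512 times its diploid level relative to other genes. Its relative expression was -0.76 ± 0.01 (log2, SD, n = 4) in monosomics and 0.20 ± 0.01 (SD, n = 3) in diploids. The difference of -0.96 (SE 0.01) was 96.5% of the log2 copy ratio, without overlap, and the exact permutation p of 0.0571 was the smallest that 4 against 3 libraries can give, or 0.114 adjusted. With mean log2(RPKM + 1) the difference was -0.62. Of 1201 genes called in edgeR, 867 lay in the block and were lower and 3 were higher there. Outside the block 192 were higher and 139 lower, with a median log2 fold change of -0.93 in the block and 0.07 outside it. The split outside the block was 273 higher and 58 lower with limma-trend, 475 and 254 with DESeq2, 109 and 45 with the compared libraries alone and 65 and 32 without diploid replicate 2.

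By the same rule, the largest rise in monosomics was that of Zm00004b027922, from 1.21 ± 0.21 CPM (SD, n = 3) to 15.5 ± 7.03 (SD, n = 4), a log2 fold change of 3.53 (SE 0.42, edgeR adjusted p = 0.00204), or 1.74 with limma-trend on log2(RPKM + 1). The largest fall was that of Zm00004b001483, from 71.8 ± 31.3 (SD, n = 3) to 7.19 ± 3.82 CPM (SD, n = 4), a log2 fold change of -3.51 (SE 0.50, edgeR adjusted p = 0.00247). The count of called genes was 657 and 710 without diploid replicates 2 and 3, 681 in a fit of the compared libraries alone and 639 with the S number as a block.

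In trisomic plants of series 2 the block was expressed at 1.41 times its diploid level relative to other genes. Its relative expression was 0.70 ± 0.01 (log2, SD, n = 3) against 0.20 ± 0.01 (SD, n = 3), a difference of 0.49 (SE 0.01) or 84.6% of the log2 copy ratio, without overlap. It was 0.60 with summed counts, above the log2 copy ratio of 0.58, and 0.35 with mean log2(RPKM + 1). The exact permutation p of 0.1 was the smallest that 3 against 3 libraries can give, or 0.15 adjusted. The trisomic effect on the block in series 1 minus that in series 2 was -0.03, with an exact permutation p of 0.808 over 1960 permutations (0.808 adjusted), in which the different baselines of the series add to the permuted spread. The median log2 fold change was 0.50 over 1797 block genes and -0.03 over 20028 others.

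Few single genes passed the test in series 2 trisomics. In edgeR 58 were called, with 16 higher and 0 lower in the block and 38 higher and 4 lower outside it. Of the 42 outside the block, 27 belong to a set of 38 identifiers with at least 10 reads in every trisomic library and at most 3 reads in all diploids together. The count was 22, 24 and 26 without diploid replicates 1, 2 and 3, and 24 and 30 without trisomic replicates 2 and 3. It was 16 with the stricter filter, 34 and 2 with the replicate number and the S number as a block, 135 in a fit of the compared libraries alone and 427 with DESeq2.

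**Figure D3:**
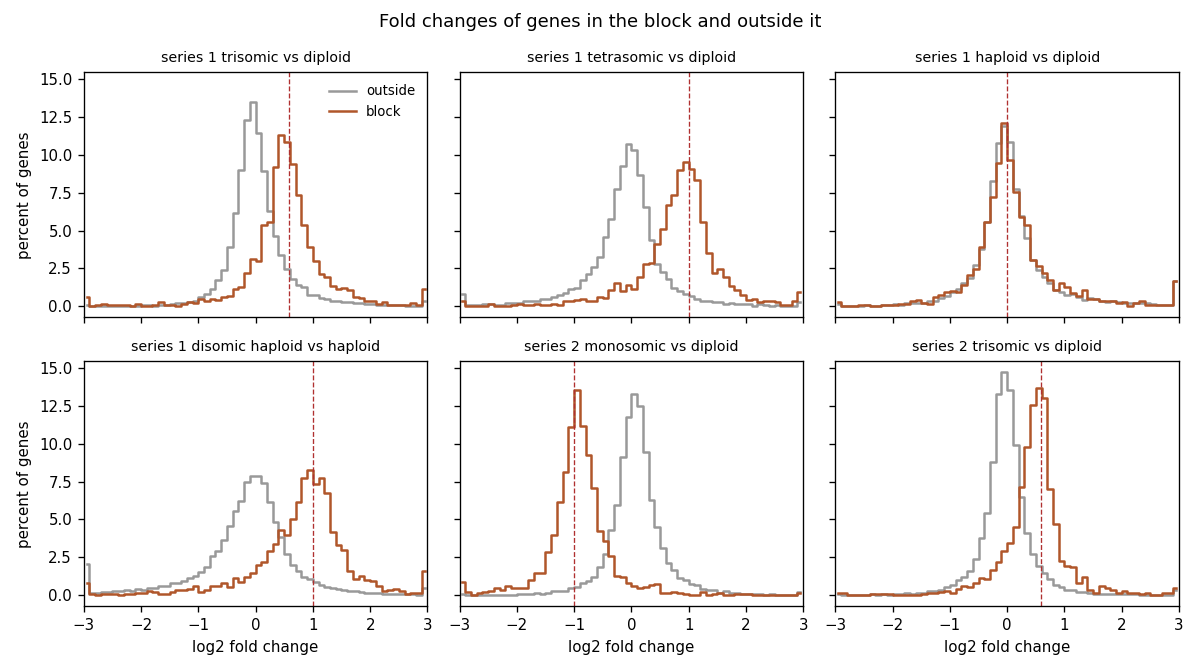
Distribution of log2 fold changes of genes in the block (orange) and outside it (grey) in percent of genes, with values beyond 3 in either direction pooled in the end bins and the log2 copy ratio of 1L as a dashed line. Block medians range from -0.93 in monosomics to 0.90 in disomic haploids, and medians outside the block from -0.08 to 0.07.

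Trends over copy number used all diploid-background libraries of a series. In series 1 edgeR called 1486 genes, with 852 rising and 3 falling per copy in the block and 204 rising and 427 falling outside it. In series 2 it called 3419 genes, with 1377 rising and 6 falling in the block and 787 rising and 1249 falling outside it. With TMM outside the block the series 2 split there was 950 rising and 1050 falling. The direction outside the block in series 1 was 255 rising and 316 falling with TMM outside the block, and turned to 263 rising and 214 falling with limma-trend. The count in series 1 was 2660 without diploid replicate 1, 946 without diploid replicate 4, 886 without tetrasomic replicate 3 and 2332 with DESeq2.

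Most block genes that could be classed had intervals that held the log2 copy ratio and not 0, here called proportional. The intervals were proportional for 835 of 1893 genes in series 1 trisomics, 1098 in tetrasomics and 973 in disomic haploids. They were proportional for 1226 of 1797 in monosomics and 737 in series 2 trisomics. Compensated genes numbered 180, 184, 211, 107 and 137 in the same order, and undecided ones 719, 464, 541, 331 and 848. Genes beyond the copy ratio numbered 109, 84, 108, 89 and 54. Those between 0 and the ratio with both excluded numbered 8, 47, 32, 35 and 0, and those changed in the opposite direction 42, 16, 28, 9 and 21. The median width on either side of an estimate was 0.55 (log2) in series 1 trisomics and 0.59 in series 2 trisomics, against a log2 copy ratio of 0.58. Intervals this wide can hardly tell a partial response from a full one in trisomics. The first 600 identifiers of the block had smaller median changes than the rest, at 0.37 and 0.54 (log2) in series 1 trisomics and 0.39 and 0.51 in series 2 trisomics. The medians were 0.74 and 0.93 in tetrasomics, 0.81 and 0.92 in disomic haploids and -0.90 and -0.94 in monosomics.

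Effects outside the block were compared between pairs of comparisons across genes, which are not independent replicates. Trisomics of the 2 series share no library, and their log2 fold changes correlated with r = 0.45 and rho = 0.46 over 19411 genes, with 0 genes called higher in both and 1 called lower in both. When series 1 trisomic and diploid libraries were reassigned, the other splits drawn gave r from -0.40 to 0.37. Trisomics and tetrasomics of series 1 share diploids and correlated with r = 0.61 and rho = 0.60, with 24 genes called higher in both, where 0.390 would be by chance, and 42 lower, where 1.17 would. Shared diploids gave a simulated r of 0.50 with genes drawn independently, with a covariance of 0.0843 against 0.258 observed. A departure of a shared library across many genes, as in diploid replicate 1, is not simulated. The gap between the covariances thus does not show an effect beyond sharing. With the diploids divided into separate pairs, r ran from 0.16 to 0.41 with a median of 0.30. Monosomics and trisomics of series 2 gave r = 0.04 and rho = -0.08, where shared diploids gave 0.54 in the same kind of simulation. The observed covariance of 0.0131 lay below the simulated 0.0763. The observed r of 0.04 was 0.185, 0.148 and 0.194 without diploid replicates 1, 2 and 3, and 0.0193, 0.0872 and 0.0129 without monosomic replicates 2, 3 and 4. Of the 38 genes called higher in these trisomics, 17 were also called higher in monosomics, where 0.364 would be by chance, and 13 of the 17 belong to the set of 38 identifiers described for series 2 trisomics. The shared diploids add to such overlaps. Between these comparisons 0 genes were lower in both, and 3 were higher in monosomics and lower in trisomics, where 0.0383 would be by chance. The trends of the series, a pair added after seeing the data, correlated with r = 0.39 and rho = 0.37. Both called 43 genes rising, where 6.95 would be shared by chance, and 147 falling, where 25.03 would. Tetrasomics and monosomics, added at the same time and with no shared library, gave r = -0.11 and rho = -0.11. Of their calls 6 were higher in tetrasomics and lower in monosomics, where 1.18 would be by chance, and 17 were the opposite, where 3.33 would be, while 0 were higher in both and 2 lower in both.

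DNA from 1 trisomic and 1 diploid plant was compared to place the end of the varied segment, without replicates. At the distal end of chromosome 1 the trisomic to diploid ratio had a median of 1.42 over the last 10 bins, from 1.2 to 1.47, where 3 copies would give 1.46 by the share of reads beyond the main change point. Over the first 190 bins the median was 0.97. The change point fell at bin 191, with an interval of 190 to 192, but at bin 263 on running medians over 50 bins and at bin 253 for bins of at least 0.3 RPKM. Between bin 191 and the end the ratio ran from 0.548 to 2.81 with a median of 1.17, so the breakpoint is not settled by these data.

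**Figure D4:**
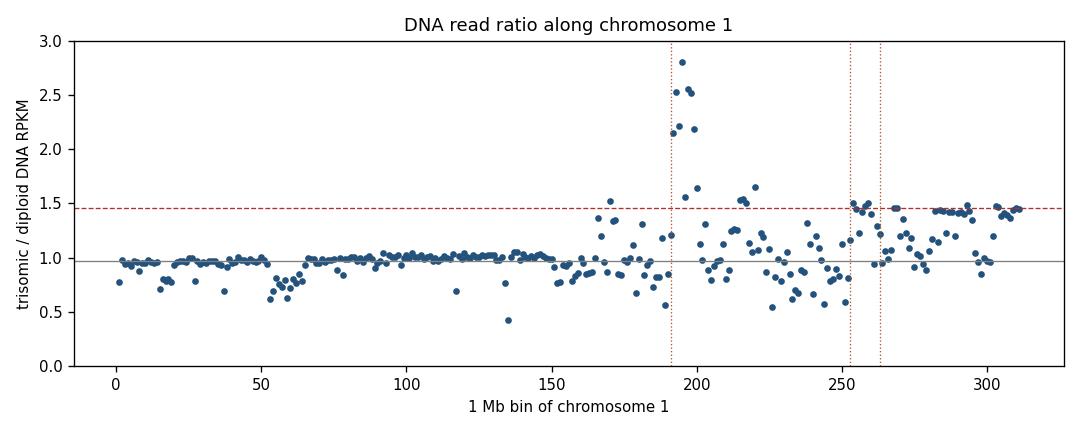
Ratio of trisomic to diploid DNA RPKM in each bin of 1 Mb along chromosome 1, with 1 library per state. The dashed line marks the ratio of 1.46 for 3 copies, the grey line that of 0.973 for the rest of the genome, and the dotted lines the change points at bins 191, 253 and 263.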

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

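The tests of the DNA bins were fixed before their result was seen. One library and one set of DNA bins stood out.

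Diploid replicate 2 of series 1 had a relative expression of the block of -0.0500, below the other diploids of its series, which ran from -0.0107 to -0.00496. Its gap to the nearest was 0.873 of the group's range; 15 sets of values were checked in this way, and chance alone makes about 1 in 20 stand out.

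The DNA table was used only for chromosome 1, but 86 bins on other chromosomes had a trisomic to diploid ratio above 1.3, up to 4.30, and most lay in 7 runs on chromosomes 2, 3, 4, 6, 7 and 8. The diploid RPKM of these bins was 0.601 of that of the 1643 bins with ratios near 1, and 83 of the 86 lay below 0.8, which argues against extra copies in the trisomic plant. Trisomic RPKM was 0.981 of the other bins, which argues against additional reads in that library. Fewer reads placed on the reference from the diploid plant may account for these 86 bins, for which a diploid level below 0.8 was needed and 0.601 was found. Which sequence differences or losses in that plant would lie behind it was not tested. Another 27 bins outside chromosome 1 had low ratios, below 1/1.3. There the diploid RPKM was 1.39 and the trisomic RPKM 0.977 of that of the bins with ratios near 1. Fewer placed diploid reads would not give that excess, so the diploid library departed in both directions. With 1 library per state, a difference between plants and one between libraries stay open.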

How the results depend on the processing

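The limits come from few libraries per group and, for trisomics, from intervals that reach about as far to either side of the estimate (a median of 0.55 and 0.59, log2) as the expected change of 0.58. For the counts of called genes, 51 of 73 values under other settings and 41 of 75 without 1 library stayed within 1.5 times the main count, or at 0. The 4 named identifiers, each in the comparison it was named for, kept their direction and their call in all 34 and 28 such values, and the dosage classes stayed within 1.5 times with TMM outside the block, the alternative run for them. For the relative expression of the block, 39 of 42 and 40 of 41 values kept their sign; p says nothing of stability there, except in series 1 trisomics, since no other comparison can give an exact p under 0.05. Causes were not tested, except where fewer genes or libraries enter by construction.

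With DESeq2 the counts of called genes rose to 1090 in series 1 trisomics, 2212 in tetrasomics, 1113 in haploids, 2678 in disomic haploids, 10 for the disomic haploid minus tetrasomic effect, 2332 for the series 1 trend and 427 in series 2 trisomics. A fit of the compared libraries alone, which estimates the spread from fewer libraries, gave 131 in series 1 trisomics, 8 in haploids, 0 in disomic haploids, 681 in monosomics and 135 in series 2 trisomics. Replicate numbers as a block gave 72 in series 1 trisomics, 137 in haploids and 34 in series 2 trisomics, and S numbers gave 639 in monosomics and 2 in series 2 trisomics. The stricter filter, which tests fewer genes, gave 249 in haploids and 16 in series 2 trisomics. No filter, which tests more genes, gave 189 in series 1 trisomics. Limma-trend gave 219 in haploids and 2 for the difference of effects.

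Without 1 library, counts ran from 49 to 699 in series 1 trisomics, 719 to 2457 in tetrasomics, 96 to 990 in haploids, 506 to 1414 in disomic haploids, 0 to 12 for the difference of effects, 886 to 2660 for the series 1 trend, 657 to 1507 in monosomics, 22 to 50 in series 2 trisomics and 2422 to 3545 for the series 2 trend. The extremes beyond 1.5 times came without diploid replicate 4 (49) and 1 (699, 2457, 2660), tetrasomic replicate 3 (719, 886), diploid replicate 2 (96), haploid replicate 2 (990), disomic haploid replicate 1 (506, 12) and 2 (12), each of which leaves 1 library assumed to vary like the other groups, and series 2 diploid replicates 2 (657) and 1 (22).

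The relative expression of the block in haploids against diploids, -0.03, turned to 0.0292 with the median over genes, 0.00299 with the stricter filter and 0.00868 with summed counts, and ran from -0.0691 to 0.000128 without 1 library, the last without haploid replicate 1. Over the other comparisons its sign held but its size moved, from 0.34 to 0.64 in series 1 trisomics, 0.63 to 1.01 in tetrasomics, 0.66 to 0.97 in disomic haploids, -0.999 to -0.62 in monosomics and 0.35 to 0.60 in series 2 trisomics, with log2(RPKM + 1) nearest to 0 in each. In series 1 trisomics it was 0.47 with the replicate block, where 4 pairs cannot give an exact p under 0.125. The correlation of monosomics with trisomics, 0.04, became -0.0842 as Spearman's rho and ran from 0.0129 to 0.194 without 1 library. The other correlations ran from 0.39 to 0.45 for trisomics of both series, 0.48 to 0.70 for trisomics and tetrasomics and 0.47 to 0.63 for tetrasomics and disomic haploids. The breakpoint, bin 191, moved to 263 with running medians and to 253 with at least 0.3 RPKM, an alternative chosen after seeing the data. The minimum of 1 RPKM was not run, as it left 1 bin.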

Other observations

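The tests of the set of 38 identifiers and of the start of the block were chosen after their patterns had been seen, as was the division of the reassignment counts by the block; the reassignments of libraries were fixed before.

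In series 2, 38 identifiers had at least 10 reads in every trisomic library and at most 3 in all diploids together, while 0 showed the reverse. They lay scattered from number 286 to 39312 with a median gap of 741, and 4 lay in the block. In monosomics 15 had reads in every library and 18 had next to none. In series 1, not used to pick them, their summed level was 35.3 to 51.8 CPM in diploids, 91.5 to 148 in trisomics and 125 to 171 in tetrasomics. It was 85.8, 0.586 and 100.1 CPM in haploid replicates 1, 2 and 3, which have no extra copy of 1L, and 56.6 and 149 in disomic haploid replicates 1 and 2.

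In series 1 haploid replicate 2 detected 0% of these identifiers, with more than 3 reads taken as detection, while the other haploids detected 81.6% and 89.5%. Transcripts of a chromosome segment that some plants carry, such as B chromosome segments of a translocation, are a candidate explanation, since 81.6% in the others with 0% in one meets what it needs, but this rests on 1 library. Alleles that differ independently at each locus were not excluded by the bound used, which needed joint absence in more than 1 library. That bound was set after the values had been seen, and by the earlier one haploid replicate 2 excluded them. Diploids at 65.8% to 73.7% lie in the range such alleles predict. Joint absences go against them in haploid replicate 2, at 0% beside 81.6%, and in disomic haploid replicate 1. The latter lies in that range at 57.9%, but it detected 2 of the 15 seen in monosomics and 16 of the other 18. Disomic haploid replicate 2 detected 14 and 16 of them. For genes switched on by extra copies of 1L, the bound for excluding it was 80% in each diploid of series 1. The diploids, which have no extra copy, detected at least 65.8%, so that bound was not met. Still, they detected 65.8% to 73.7%, and haploid replicates 1 and 3 detected 89.5% and 81.6%. Of the 18 with next to none in monosomics, series 1 diploids detected 11 to 13. These values argue against extra copies being needed for reads from the identifiers detected there. A rise of their level with extra copies stays open.

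The first 600 identifiers of the block changed less than the rest in trisomics, by a mean of -0.32 (log2, SE 0.05) in series 1 and -0.13 (SE 0.04) in series 2, and in tetrasomics by -0.15 (SE 0.05), while disomic haploids gave -0.11 (SE 0.06). Monosomics, which have no extra copy, also changed less at the start, with 0.10 (SE 0.04), but with 0.03 (SE 0.03) among block genes at or above the median level. These SE and those below run over genes, which are not independent replicates, and do not measure the spread between libraries. Count levels were similar, with medians of 12.05 CPM at the start and 12.65 in the rest in series 1 and 10.18 and 11.62 in series 2. Among block genes at or above the median level the trisomic differences were -0.20 (SE 0.0394) and -0.146 (SE 0.0308). With similar levels, this argues against lower counts as the whole cause, within the limit of such SE. The bound was 0, moved from -0.1 after other values had been seen, and series 2 lay below -0.1 by less than 2 SE. Medians of -0.90 in monosomics and 0.74 in tetrasomics argue against a start outside the varied segment. Sequence differences between the extra copy and the reference stay open, as the spread of log2 changes was at least 1.61 times that of the rest in trisomics of both series but 1.26 times in tetrasomics and 1.05 times in disomic haploids. Tetrasomics and disomic haploids were added to this test after the values had been seen. Other differences between the parents of the extra copy and of the diploids were not tested and stay open.

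Reassigning the libraries of a comparison asks how often chance gives as high a count. With 35 splits the smallest possible share is 1 of 35, and no share was adjusted for the number of counts examined. In monosomics 1 of 35 splits, the real one, reached 1201 and the highest other gave 221. For the trends, 80 of 27720 possible reassignments were drawn in series 1 and 80 of 4200 in series 2. The real one alone, 1 of 80, reached 1486 in series 1 (highest other 2) and 3419 in series 2 (highest other 1617). Arbitrary orders of the libraries thus seldom give such counts. So few draws can miss groupings near the real one, such as the exchange that passed the real count in series 1 trisomics. For series 1 trisomics, with 80 of 126 possible splits drawn, 2 of 80 reached 340, a share under 0.05. The highest other gave 1103, above the real count, so the total does not settle it. In the block 1 of 80, the real split, reached 235 and the highest other gave 137. Outside the block 2 of 80 reached 105 and the highest other gave 966, a split that points to another structure, described next. For tetrasomic calls in the block, 1 of 35, the real split, reached 830 and the highest other gave 606. Chance could not be excluded for the tetrasomic calls outside the block, where 2 of 35 reached 570 and the highest other gave 1783. The same held for the total, where 2 of 35 reached 1400 and the highest other gave 2389. In haploids chance could not be excluded either. There 2 of 35 reached 424 in all (highest other 1160), 34 in the block (103) and 390 outside it (1057). For series 2 trisomics, 10 splits are too few for a share under 0.05; the real count was 58 and the highest other 0.

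The split of series 1 trisomics and diploids that gave 1103 exchanged diploid replicate 1 with trisomic replicate 1. That for haploids, 1160, exchanged diploid replicate 1 with haploid replicate 2. In tetrasomics the highest, 2389, set diploid replicates 2, 3 and 4 apart from diploid replicate 1 and the tetrasomics, so that it kept most of the real contrast. These counts exceed the real ones and point to a structure of the series 1 libraries that the groups do not describe. For the correlation of the trends between the series outside the block, 80 of 27720 possible reassignments of series 1 were drawn. Of these 1 of 80 reached the real 0.386 and the highest other gave 0.368.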
